A study of Homo sapiens with 21 samples.

How the data were processed

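MCF7 cells were measured on 21 arrays, 3 for the untreated control and 3 for each of 6 times of exposure to 5 µM azacytidine. Per the labels, total RNA was copied to cRNA labelled with biotin and read in 1 colour. Samples were grouped by their titles, which give the time and a replicate number from 1 to 3. Each array holds 54840 gene probes, 360 positive and 384 negative control spots. Per the file headers, each deposited array file gives for every spot the mean intensity, the local background median intensity, a background-subtracted intensity, a normalized intensity and a quality flag, on a linear scale. Checked on the values, the subtracted intensity was the spot mean minus the background median to within 5.00e-12, and the authors' normalized intensity was the subtracted one divided by 1 factor per array to within a relative 9.31e-15. The authors' table of the whole series held the same normalized intensities. Its medians over gene probes were 0.991, 0.993 and 0.993 in the control, 0.996, 0.997 and 0.998 at 1 h, 0.996, 0.996 and 0.996 at 2 h, 0.997, 0.997 and 0.997 at 3 h, 0.994, 0.994 and 0.993 at 4 h, 0.998, 0.998 and 0.998 at 6 h and 0.993, 0.992 and 0.993 at 12 h, so the scale is linear with each array divided to a median near 1, and as 1-colour data have no ratio to turn, none of scale, centring and direction stays unknown. The software that set the flags is not given in the sources used here, nor is a slide or a scan date.

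Intensities were processed with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. Spots flagged as irregular, contaminated or masked were left out, the background was corrected by normexp with an offset of 50, values were quantile normalized between arrays and taken to log2, and control spots were removed after the background step. A probe was kept when flagged good on at least 3 of the 21 arrays, which left 30280 probes, 12789 of them good on all 21. No pair of arrays held identical values, and Spearman's rho between arrays of 1 group ran from 0.794 to 0.930. Array number and signal over background limit the precision, since arrays carry no counts. The offset stays in the normalized intensities, so changes and folds are generally smaller than those of the signal without it, most for dim probes. A probe not flagged good on any array of a group has only a bound there. For such probes the fold is given as at least the mean of the brighter group over the mean, per array, of the higher of the lowest good signal and the probe's own.

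Probes carry a GenBank or RefSeq accession and no gene name in the files. Names were taken by matching unversioned RefSeq accessions to a table of human genes of assembly GRCh38.p14, used for names only. Of 15871 probes with a RefSeq accession 14513 matched and 1358 did not, and 38969 probes had another accession and stayed unnamed. The kept probes covered 9859 named genes, 599 of them with several probes, and a gene was taken at its brightest probe by mean over all arrays. Among the genes picked by the rule given below, another probe of the same gene was called in the opposite direction for SSX2 at 3 h, DLC1 at 4 h and 12 h and EHMT2 at 12 h. The remaining genes with several probes were not checked for this. No genome coordinates are given, because the files name no build.

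A linear model with 7 group means was fitted to all 21 arrays with lmFit and eBayes. Tests were each time minus control, the mean of the 6 treated times minus control, a slope per doubling of time over the 18 treated arrays, and a moderated F test over the 6 times, each adjusted by Benjamini-Hochberg over the probes tested at a threshold of 0.05. Gene lists of stress responses, the cell cycle, nucleic acid and protein metabolism, DNA methylation, signalling and cell types, 32 in number, were tested with camera at a preset correlation between genes of 0.01. The direction that camera gives is that of the list against all other named genes, each at its brightest probe. Lists were tested again with an estimated correlation and with fry. Each test was adjusted over the 30 lists with at least 5 usable members. The metallothionein list and the leukocyte list had fewer usable members and were not tested. A missing value of a list gene was set to its group's mean.

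The genes named were fixed by rule. At each time these are the 10 that rose and the 10 that fell most among named probes past the threshold whose 3 treated arrays all lay beyond the 3 controls and that were good on all 3 arrays of the brighter group, with the same rule without the non-overlap for the slope. Within a list, up to 4 members past the threshold with the largest change were picked, or up to 2 with the lowest p where none passed. DNMT1, DNMT3A and DNMT3B were picked at every time. Only some of the picked list members are printed below, while counts of named values cover all genes picked. Of the genes that the rule names, 1 is not reported here. The lists, the tests, the rule and most alternatives were fixed before the data were examined. Settings chosen in advance besides these were array medians set equal, cyclic loess, the authors' normalized intensities, background subtraction without offset, no filter on dim probes, probes good on all arrays, eBayes with trend and robust options, array weights, 1 probe per gene, the replicate number as a block, arrays left out 1 at a time, the 5 arrays with another time in their note left out, a fit of only the 6 arrays compared, and a log2 change of at least 1. Fits of the 12 arrays of higher signal, slopes within each signal level and the background fit with flagged spots kept were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

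The steps were tested on simulated data. Values for 30280 probes were drawn from the control means and the within-group spread, with sets of 67 probes changed by log2 0.5 or 1 at a single time. Changes of 1 (log2) were recovered for 98.5% at 2 h and 88.1% at 6 h, and changes of 0.5 for 53.7% and 53.7%. Among the unchanged probes of those simulations 47 were called at 1 h, 6 at 3 h and 15 at 6 h, and 0, 0 and 1 at 2, 4 and 12 h. At 1 h the simulation recovered 47.8% of 67 probes changed by 0.5 and 91.0% of 67 changed by 1. It also recovered 100% of a further 66 changed by 2. The 47 false calls were thus a larger share of all simulated calls at 1 h than the threshold for adjusted p-values allows. At 6 h 98.5% of a further 66 probes changed by 2 were recovered. The 15 false calls at 6 h were likewise a larger share of all simulated calls than the threshold allows. A list shifted by 0.5 was called at each of the 6 times, with 0 other lists called. Noise was drawn independently for each probe, so the simulation holds no test of false list calls among correlated genes.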

Results

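MCF7 cells, an established line of human breast cancer cells that express the estrogen receptor, were exposed to 5 µM azacytidine, a cytidine analog that is incorporated into RNA and DNA and traps DNA methyltransferases. The question named by the study's title is how transcript levels moved with time of exposure. RNA was measured on 1-colour arrays in 7 groups of 3 arrays, an untreated control and cells treated for 1, 2, 3, 4, 6 and 12 h, 21 arrays in all. The series' design text calls the replicates biological and says that plates were seeded from a common pool, so the spread given here is that between plates of cells. The control is described only as untreated, with no time of its own and no solvent named. The treatment note of 5 arrays (all 3 at 3 h, and replicate 1 at 4 h and at 6 h) gives another time than their title and description, and the title was used.

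Array signal differed between groups, although the design text calls the raw medians of the arrays similar. The median net signal of the gene probes was 22 to 31.4 intensity units on the 12 arrays of the control, 2, 4 and 12 h groups, with 47.1 to 53% of probes flagged good in the files. It was 10.6 to 15.9 on the 9 arrays of the 1, 3 and 6 h groups, with 31.6 to 40.8% good. The median within-group SD was 0.08 (log2) in the control and 0.08, 0.09 and 0.11 at 2, 4 and 12 h, against 0.20, 0.16 and 0.17 at 1, 3 and 6 h. The files also number the arrays, with no stated meaning, and the 9 arrays of lower signal carry the numbers 0 to 8, of which 7 recur among the other 12. Each time lies wholly at 1 signal level and the control at the higher one, so for 1, 3 and 6 h signal level and treatment cannot be told apart. The times at the higher level are therefore described first. Within that level the control arrays, at 28.2 to 31.4, lay above all arrays at 2 h (25.7 to 27.7) and 4 h (23.2 to 24.6). The 12 h arrays, at 22.0 to 28.5, overlapped with the control. Signal and treatment therefore cannot be fully told apart at 2 and 4 h either, though the difference in signal is smaller. Changes are log2 differences of normalized intensity, treated minus control, ± SE with 3 arrays per group, and adjusted p-values are limma's after Benjamini-Hochberg adjustment. The SE is limma's moderated one and rests on 1 spread per probe shared by all 7 groups. It therefore does not measure the spread of the 6 arrays compared, and the SDs above differed between groups.

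**Figure D1:**
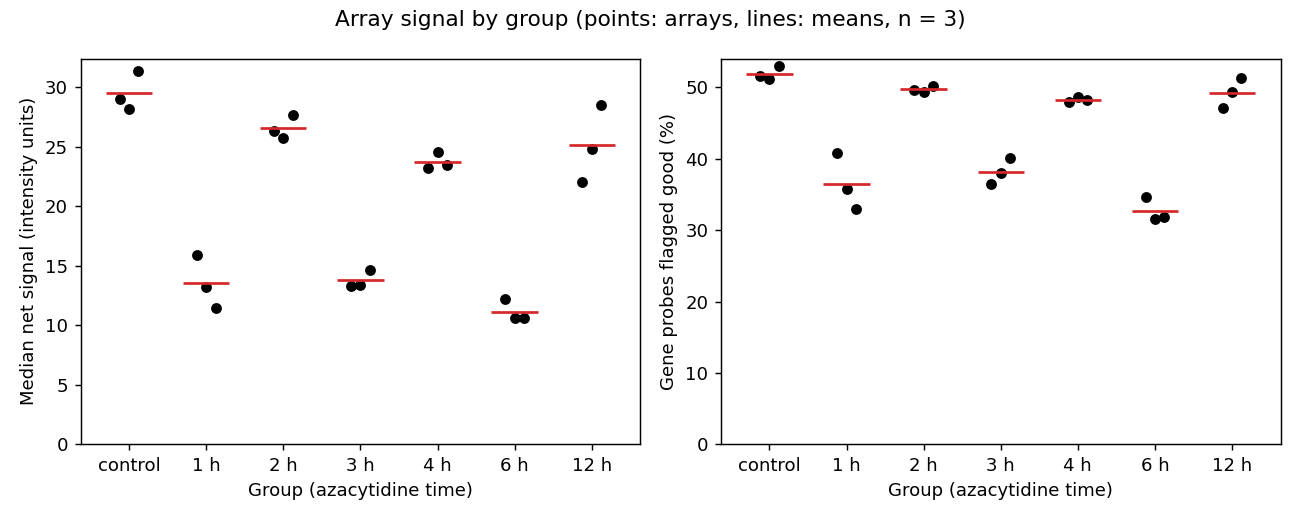
Each point is 1 array, placed by group on the horizontal axis, and red lines are means of 3 arrays. The left panel gives the median net signal in intensity units and the right panel the percentage of gene probes flagged good, and both were lower on the 9 arrays of the 1, 3 and 6 h groups than on the other 12.

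At 2 h the largest changes among the named genes were falls. TXNIP, which encodes a thioredoxin-binding protein, fell by 2.30 ± 0.22 on the log2 scale (adjusted p = 5.58e-06), a 4.91-fold lower intensity. KCNJ8 (-1.94 ± 0.23), PNRC1 (-1.64 ± 0.22) and EFNA1 (-1.40 ± 0.22) also fell, as did ZNF16 (-1.37 ± 0.12), CCNL1 (-1.34 ± 0.17), CLK1 (-1.25 ± 0.19) and CSTF1 (-1.32 ± 0.19), of which CCNL1 and CLK1 act in RNA splicing and CSTF1 in 3′ end cleavage. The transcription factor ELF3 (-1.29 ± 0.17) and MTSS1 (-1.22 ± 0.15) fell too. The largest rises were CCL26 (1.40 ± 0.15), BCAS3 (1.24 ± 0.34), LOXL1 (1.17 ± 0.32), PPARG (1.16 ± 0.20) and CST6 (1.06 ± 0.23), followed by SPANXC (0.89 ± 0.20), PTPN11 (0.88 ± 0.15), CCDC86 (0.79 ± 0.13) and ABCG2 (0.78 ± 0.19). TGFA was not well above background in the control, and was at least 1.65-fold higher. Leaving out 1 array ended the calls of BCAS3 (without control 2 or 2 h array 1, 2 or 3, adjusted p up to 0.144), LOXL1 (without control 2 or 2 h array 1, 2 or 3, adjusted p up to 0.149), CST6 (without 2 h array 2, adjusted p up to 0.0683), SPANXC (without control 2 or 2 h array 2, adjusted p up to 0.113) and ABCG2 (without control 1 or 3 or 2 h array 1, 2 or 3, adjusted p up to 0.140).

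Among the fixed lists, p53 target genes went down at 2 h. Among 23 measured p53 target genes, 0 rose and 5 fell, or 0 and 6 adjusted over the list alone. p53 target genes had a median log2 change of -0.14 and a camera adjusted p = 0.00200, or an adjusted p = 0.0545 with an estimated correlation. Those that fell included BTG2 (-1.13 ± 0.15), PPM1D (-1.03 ± 0.16), TP53INP1 (-0.97 ± 0.16) and SESN1 (-0.80 ± 0.15). Luminal breast epithelial genes also went down, with falls of ESR1 (-0.84 ± 0.20), MUC1 (-0.61 ± 0.17) and GATA3 (-0.59 ± 0.10); ESR1 encodes the estrogen receptor. Among 16 measured luminal breast epithelial genes, 0 rose and 3 fell, or 0 and 6 adjusted over the list alone. Luminal breast epithelial genes had a median log2 change of -0.31 and a camera adjusted p = 0.000486, or an adjusted p = 0.0545 with an estimated correlation. Proteasome subunits and ribosome biogenesis genes went up, with PSMD12 (0.44 ± 0.12) and RRS1 (0.59 ± 0.12) and DKC1 (0.48 ± 0.11) rising and NOP2 (-0.72 ± 0.18) falling. Among 16 measured proteasome subunits, 1 rose and 0 fell, or 3 and 0 adjusted over the list alone. Proteasome subunits had a median log2 change of 0.19 and a camera adjusted p = 0.00926, or an adjusted p = 0.0545 with an estimated correlation, while the median turned to -0.044 with array medians set equal (camera adjusted p = 0.199, direction up). Among 21 measured ribosome biogenesis genes, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone. Ribosome biogenesis genes had a median log2 change of 0.20 and a camera adjusted p = 0.0433, or an adjusted p = 0.331 with an estimated correlation, while the median turned to -0.0062 with array medians set equal (camera adjusted p = 0.301, direction up). In all, 308 probes were higher and 918 lower of 30171 tested, 6 and 58 of them by 2-fold or more. Under other scalings at 2 h these counts were 304 and 5116 with array medians set equal, 80 and 1359 with the authors' values and 1285 and 2880 with cyclic loess. The count was 576, 318 or 541 without 2 h replicate 1, 2 or 3 and 712 or 458 without control replicate 1 or 2, and without control replicate 1 the lists called were 7. It was 4576 when only the 12 arrays of higher signal were fitted, and none of the 4 list calls held with the estimated correlation. At least 4 lists were also called in 6 of the 10 splits of these 6 arrays, the real split among them. Of the list genes, ESR1 (without control 2 or 2 h array 2, adjusted p up to 0.145), MUC1 (without control 2 or 2 h array 1, 2 or 3, adjusted p up to 0.312), PSMD12 (without control 1 or 2 or 2 h array 1, 2 or 3, adjusted p up to 0.201), DKC1 (without control 3 or 2 h array 2 or 3, adjusted p up to 0.0697) and NOP2 (without control 1 or 2 or 2 h array 1, 2 or 3, adjusted p up to 0.132) lost their calls with 1 array left out.

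At 4 h the gene with the largest rise was CHAC1, which encodes a glutathione-degrading enzyme of the amino acid response, at 2.23 ± 0.15 or 4.70-fold (adjusted p = 4.49e-08). Of 18 measured genes on the list of that response 2 rose, CHAC1 and NUPR1 (0.52 ± 0.17), and 2 fell, TRIB3 (-1.02 ± 0.21) and ATF4 (-0.85 ± 0.21), or 2 and 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.811). LYAR (1.83 ± 0.57), GRPEL2 (1.51 ± 0.32), CCL26 (1.47 ± 0.15), LOXL1 (1.32 ± 0.32) and BCAS3 (1.27 ± 0.34) rose too, as did RASGRP1 (1.15 ± 0.22), BRIX1 (1.13 ± 0.20), ZNRF4 (1.07 ± 0.32) and UPK3B (1.05 ± 0.24). The falls were led by KCNJ8 (-2.17 ± 0.23), NOP2 (-1.94 ± 0.18), TXNIP (-1.92 ± 0.22), MPHOSPH10 (-1.87 ± 0.19) and PNRC1 (-1.86 ± 0.22), where NOP2 is an rRNA cytosine methyltransferase and MPHOSPH10 a component of the small-subunit processome. RBM23 (-1.85 ± 0.15), CSTF1 (-1.79 ± 0.19), TRIM33 (-1.78 ± 0.16), YTHDF2 (-1.72 ± 0.18) and SFSWAP (-1.70 ± 0.12) fell as well. With 1 array left out, calls ended for NUPR1 (without control 1 or 2 or 4 h array 2 or 3, adjusted p up to 0.189), ATF4 (without control 2 or 4 h array 3, adjusted p up to 0.0825), LYAR (without 4 h array 1, 2 or 3, adjusted p up to 0.143), BCAS3 (without control 2 or 4 h array 2 or 3, adjusted p up to 0.0590), ZNRF4 (without control 1 or 4 h array 1, 2 or 3, adjusted p up to 0.121) and UPK3B (without control 2, adjusted p up to 0.0548).

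G2/M genes went down at 4 h. Among 23 measured G2/M genes, 0 rose and 11 fell, or 1 and 11 adjusted over the list alone. G2/M genes had a median log2 change of -0.30 and a camera adjusted p = 0.00567, or an adjusted p = 0.447 with an estimated correlation. AURKA (-1.64 ± 0.24), CENPF (-1.27 ± 0.15), TTK (-1.08 ± 0.15) and HMMR (-1.08 ± 0.18) were among those that fell, and all 4 encode mitotic proteins. Luminal genes went down, with KRT19 (-1.14 ± 0.22), ESR1 (-0.92 ± 0.20) and CLDN3 (-0.64 ± 0.14) falling. Among 16 measured luminal breast epithelial genes, 0 rose and 5 fell, or 0 and 7 adjusted over the list alone. Luminal breast epithelial genes had a median log2 change of -0.36 and a camera adjusted p = 0.0199, or an adjusted p = 0.282 with an estimated correlation. Immediate early genes went up, with IER2 (0.88 ± 0.14), ZFP36 (0.66 ± 0.13) and KLF10 (0.56 ± 0.15) rising and MYC (-0.73 ± 0.17) falling. Among 15 measured immediate early genes, 3 rose and 1 fell, or 3 and 1 adjusted over the list alone. Immediate early genes had a median log2 change of 0.14 and a camera adjusted p = 0.0496, or an adjusted p = 0.205 with an estimated correlation. Genes with promoter methylation in breast tumours went up, with CST6 (0.91 ± 0.23) and DLC1 (0.45 ± 0.11) rising, although another DLC1 probe was called in the opposite direction, and proteasome subunits likewise. For CST6 the SD was 0.84 (log2) in the control and 0.039 at 4 h, and the same control arrays enter its change at 2 h. Among 17 measured genes with promoter methylation in breast tumours, 2 rose and 0 fell, or 2 and 0 adjusted over the list alone. Genes with promoter methylation in breast tumours had a median log2 change of 0.17 and a camera adjusted p = 0.0199, or an adjusted p = 0.245 with an estimated correlation, while the median turned to -0.044 with array medians set equal (camera adjusted p = 0.0642, direction up). Among 16 measured proteasome subunits, 2 rose and 0 fell, or 2 and 0 adjusted over the list alone. Proteasome subunits had a median log2 change of 0.27 and a camera adjusted p = 0.0136, or an adjusted p = 0.161 with an estimated correlation. In all, 1448 probes were higher and 2199 lower of 30218 tested, 29 and 211 of them by 2-fold or more. Under other scalings at 4 h these counts were 930 and 7725 with array medians set equal, 530 and 2898 with the authors' values and 2766 and 4661 with cyclic loess. Without 4 h replicate 2 or 3 the count was 2098 or 1626 and without control replicate 1 or 2 2313 or 1780, and the lists called were 3 without 4 h replicate 2 and 2 without control replicate 2. The fit of the 12 arrays of higher signal gave 8701 probes, and none of the 5 list calls held with the estimated correlation. With array medians set equal only 2 lists were called at 4 h. The calls of KLF10 (without control 1 or 2 or 4 h array 3, adjusted p up to 0.145) and DLC1 (without 4 h array 3, adjusted p up to 0.0629) were lost with 1 array left out.

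At 12 h genes of the amino acid response, which are targets of the transcription factor ATF4, were up. Among 18 measured amino acid response genes (ATF4 targets), 10 rose and 0 fell, or 10 and 0 adjusted over the list alone. Amino acid response genes (ATF4 targets) had a median log2 change of 0.43 and a camera adjusted p = 3.71e-12, or an adjusted p = 0.00125 with an estimated correlation. CHAC1 rose by 3.14 ± 0.15 (8.80-fold, adjusted p = 2.53e-11), and ATF3 (2.46 ± 0.13), TRIB3 (1.77 ± 0.21) and SESN2 (1.68 ± 0.11) rose with it. The stress cytokine gene GDF15 (2.87 ± 0.20), the growth arrest gene GADD45A (2.12 ± 0.18), TGM1 (1.83 ± 0.12), TNFRSF12A (1.78 ± 0.17), ZNF24 (1.88 ± 0.20) and ZNF281 (1.77 ± 0.20) and NIBAN1 also rose. NIBAN1, not well above background in the control, was at least 5.27-fold higher. The falls were led by KCNJ8 (-3.13 ± 0.23), MSMB (-2.29 ± 0.30), EMP2 (-2.21 ± 0.19), FA2H (-1.99 ± 0.26) and C1QTNF6 (-1.77 ± 0.27), then MGP (-1.74 ± 0.18), LTBP1 (-1.70 ± 0.15), HSPA1A (-1.70 ± 0.14), RMND1 (-1.58 ± 0.18) and METAP2 (-1.57 ± 0.21).

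Several other lists moved at 12 h. Apoptosis regulators went up, with PMAIP1 (1.56 ± 0.19), HRK (0.96 ± 0.12), MCL1 (0.79 ± 0.10) and BAK1 (0.59 ± 0.13) rising; PMAIP1, HRK and BAK1 promote apoptosis and MCL1 opposes it. Among 15 measured apoptosis regulators, 4 rose and 0 fell, or 5 and 1 adjusted over the list alone. Apoptosis regulators had a median log2 change of 0.24 and a camera adjusted p = 0.00580, or an adjusted p = 0.0337 with an estimated correlation, while the median turned to -0.10 with array medians set equal (camera adjusted p = 0.0142, direction up). Genes of P-TEFb, the kinase complex that releases paused RNA polymerase II, and of transcription elongation went up, with CCNT2 (0.76 ± 0.16), CCNT1 (0.53 ± 0.12), CDK9 (0.52 ± 0.12) and BRD4 (0.43 ± 0.11) rising. Among 13 measured P-TEFb and transcription elongation genes, 5 rose and 0 fell, or 7 and 0 adjusted over the list alone. P-TEFb and transcription elongation genes had a median log2 change of 0.42 and a camera adjusted p = 0.00528, or an adjusted p = 0.0337 with an estimated correlation. p53 target genes were split, with GDF15 (2.87 ± 0.20) and GADD45A (2.12 ± 0.18) rising and CCNG1 (-1.07 ± 0.18) falling. Among 23 measured p53 target genes, 9 rose and 6 fell, or 11 and 6 adjusted over the list alone. p53 target genes had a median log2 change of 0.20 and a camera adjusted p = 0.0102, or an adjusted p = 0.0693 with an estimated correlation. Immediate early genes and replication dependent histones went up, with KLF4 (1.36 ± 0.14), IER2 (1.18 ± 0.14) and H3C1 (0.61 ± 0.11) among the rises. Among 15 measured immediate early genes, 4 rose and 1 fell, or 4 and 1 adjusted over the list alone. Immediate early genes had a median log2 change of 0.13 and a camera adjusted p = 0.0130, or an adjusted p = 0.0607 with an estimated correlation, while the median turned to -0.0016 with array medians set equal (camera adjusted p = 0.0118, direction up). Among 13 measured replication dependent histones, 2 rose and 0 fell, or 3 and 0 adjusted over the list alone. Replication dependent histones had a median log2 change of 0.32 and a camera adjusted p = 0.0112, or an adjusted p = 0.106 with an estimated correlation.

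Heat shock genes went down at 12 h, and HSPA1A (-1.70 ± 0.14), HSPH1 (-1.33 ± 0.15), HSPA8 (-1.03 ± 0.11) and DNAJA1 (-0.97 ± 0.15) fell. Among 13 measured heat shock genes, 0 rose and 6 fell, or 0 and 6 adjusted over the list alone. Heat shock genes had a median log2 change of -0.28 and a camera adjusted p = 0.00528, or an adjusted p = 0.101 with an estimated correlation. Cholesterol synthesis genes went down, with INSIG1 (-0.96 ± 0.20), SQLE (-0.79 ± 0.12) and FDFT1 (-0.78 ± 0.18) falling. Among 16 measured cholesterol synthesis genes, 1 rose and 9 fell, or 1 and 9 adjusted over the list alone. Cholesterol synthesis genes had a median log2 change of -0.49 and a camera adjusted p = 0.00595, or an adjusted p = 0.106 with an estimated correlation. Luminal genes went down, with AGR2 (-1.38 ± 0.15), ESR1 (-1.02 ± 0.20), MUC1 (-0.99 ± 0.17) and CDH1 (-0.75 ± 0.19) falling, and so did G1/S and DNA replication genes, with GINS2 (-1.41 ± 0.17), MCM3 (-1.04 ± 0.11), CCNE1 (-0.76 ± 0.20) and PCNA (-0.73 ± 0.16) falling. Among 16 measured luminal breast epithelial genes, 1 rose and 9 fell, or 1 and 9 adjusted over the list alone. Luminal breast epithelial genes had a median log2 change of -0.64 and a camera adjusted p = 0.00502, or an adjusted p = 0.0813 with an estimated correlation. Among 21 measured G1/S and DNA replication genes, 0 rose and 6 fell, or 0 and 6 adjusted over the list alone. G1/S and DNA replication genes had a median log2 change of -0.17 and a camera adjusted p = 0.0227, or an adjusted p = 0.0909 with an estimated correlation. The progesterone receptor gene PGR, an estrogen-induced gene, fell by 1.48 ± 0.13. In all, 2550 probes were higher and 2778 lower of 30218 tested, 221 and 261 of them by 2-fold or more. Under other scalings at 12 h these counts were 1786 and 8672 with array medians set equal, 1007 and 4264 with the authors' values and 4845 and 3725 with cyclic loess. Without replicate 1 of the 12 h group 3301 passed, and 9237 passed in the fit of the 12 arrays of higher signal; of the 10 list calls, those of the amino acid response, the apoptosis regulators and the P-TEFb list held with the estimated correlation. Single arrays ended the calls of CCNE1 (without 12 h array 3, adjusted p up to 0.0565) and CCNT1 (without 12 h array 1, adjusted p up to 0.0509).

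**Figure D2:**
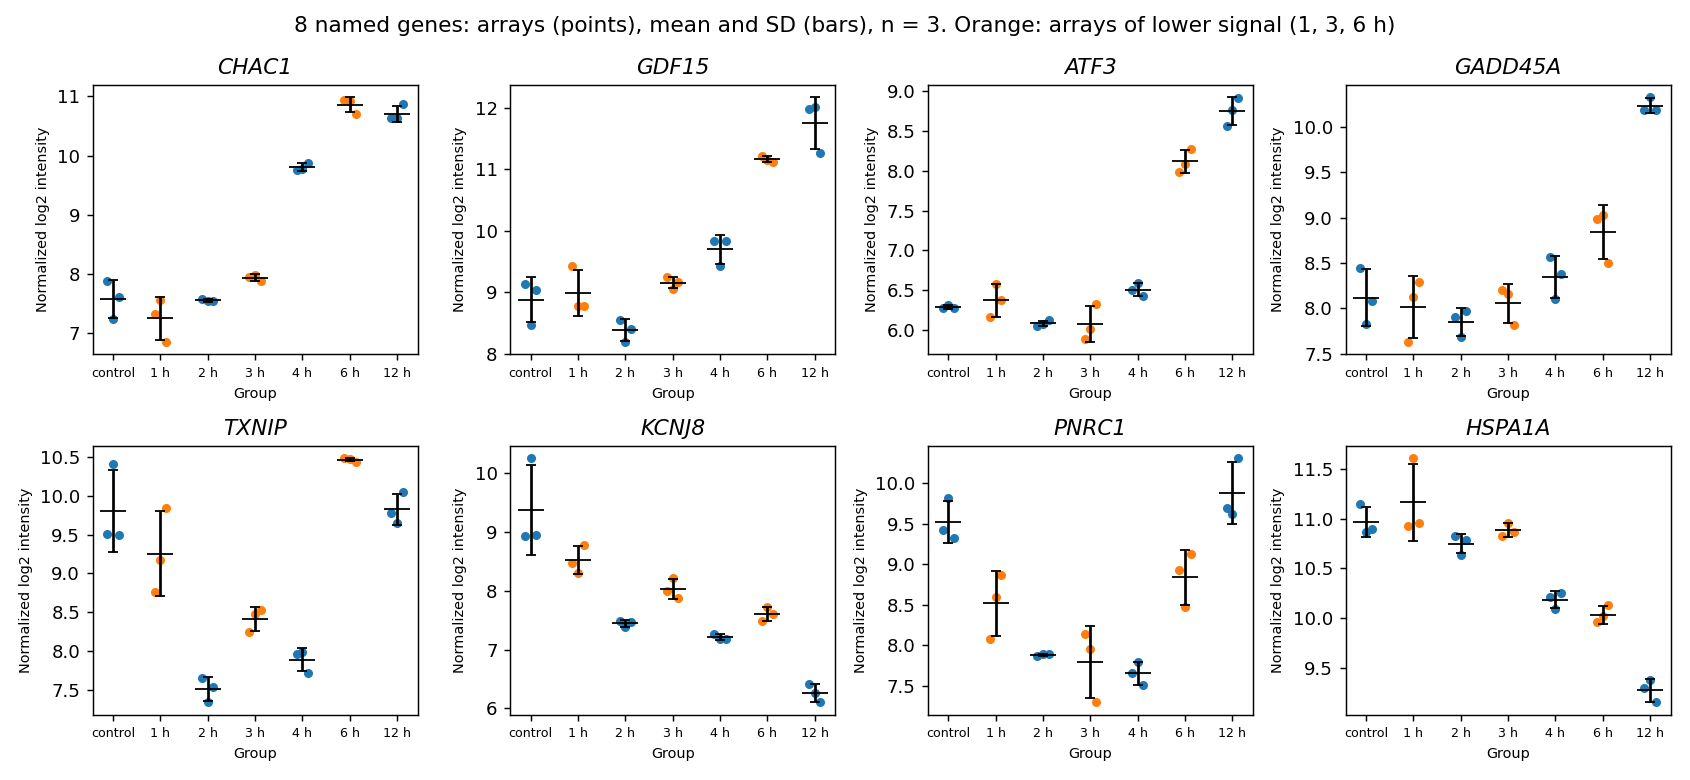
Normalized log2 intensity of 8 named genes, 1 panel per gene, against group. Points are arrays, bars are mean and SD of 3 arrays, and orange marks the 1, 3 and 6 h arrays of lower signal. CHAC1 rose at 4, 6 and 12 h, and TXNIP and PNRC1 fell at 2 and 4 h.

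**Figure D3:**
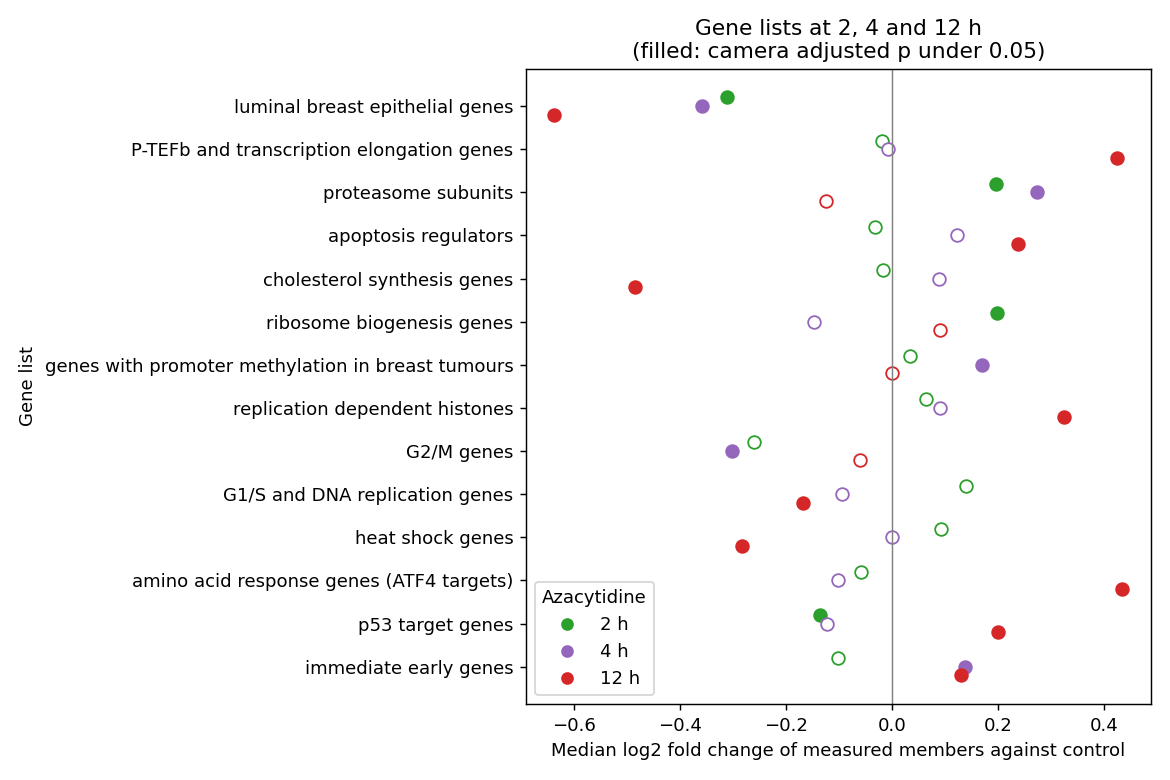
Median log2 fold change against control over the measured members of each list with a camera call at 2, 4 or 12 h. Filled points have a camera adjusted p below 0.05 with the preset correlation, and open points do not. With array medians set equal, which put the median probe at -0.10, -0.14 and -0.15 at 2, 4 and 12 h, the medians of ribosome biogenesis genes and proteasome subunits at 2 h, of genes with promoter methylation at 4 h and of immediate early genes and apoptosis regulators at 12 h turned below 0.

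At 1 h, on arrays of lower signal, RBBP7 (1.92 ± 0.41), ARCN1 (1.81 ± 0.57), MTX1 (1.76 ± 0.34), H2BC5 (1.63 ± 0.24) and H2BC12 (1.60 ± 0.26) were higher than in the control, as were CYBA (1.49 ± 0.17), ANXA9 (1.44 ± 0.18), BCAS3 (1.39 ± 0.34), TMBIM6 (1.38 ± 0.18) and ACTG1 (1.37 ± 0.20). WASL (-1.61 ± 0.21), ANKRD12 (-1.55 ± 0.19), DECR1 (-1.51 ± 0.26), P2RX3 (-1.41 ± 0.29) and GPN2 (-1.38 ± 0.19) were lower, as were UBA52 (-1.32 ± 0.20), BPTF (-1.27 ± 0.18), ZFYVE1 (-1.25 ± 0.17), NPR1 (-1.24 ± 0.32) and ATRX (-1.23 ± 0.12). Immediate early genes went down, with falls of ZFP36 (-1.02 ± 0.13), KLF10 (-0.84 ± 0.15) and MYC (-0.74 ± 0.17). Among 15 measured immediate early genes, 0 rose and 5 fell, or 0 and 5 adjusted over the list alone. Immediate early genes had a median log2 change of -0.24 and a camera adjusted p = 0.00296, or an adjusted p = 0.0289 with an estimated correlation. The camera call of immediate early genes was lost with array medians set equal. Replication dependent histones went up. Among 13 measured replication dependent histones, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone. Replication dependent histones had a median log2 change of 0.24 and a camera adjusted p = 0.0400, or an adjusted p = 0.313 with an estimated correlation, while the median turned to -0.13 with array medians set equal (camera adjusted p = 0.0796, direction up). In all, 2340 probes were higher and 3574 lower of 30172 tested, 153 and 212 of them by 2-fold or more. Under other scalings at 1 h these counts were 268 and 19823 with array medians set equal, 436 and 9064 with the authors' values and 2974 and 3677 with cyclic loess. In the main fit the balance was the other way among the 9824 named genes tested, with 1278 higher and 841 lower. Leaving out 1 array ended the calls of ARCN1 (without 1 h array 1, 2 or 3, adjusted p up to 0.0733) and NPR1 (without 1 h array 2, adjusted p up to 0.0744). Of the 105 named values past the threshold at this time, 46 changed sign when array medians were set equal, a scaling that put the median probe at -0.51 (log2). The count was 3546 without control replicate 3, the lists called were 1 without 1 h replicate 2 or 3, and the count was 3156 in a fit of the 6 arrays compared. In the simulated data the share of false calls at 1 h was above the threshold. The main counts at 1 h may therefore hold more false calls than the threshold allows.

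At 3 h, again on arrays of lower signal, H2BC5 (1.71 ± 0.24), LYAR (1.70 ± 0.57), SYNGR2 (1.45 ± 0.19), RBBP7 (1.41 ± 0.41) and CFL2 (1.40 ± 0.46) were higher, followed by GSTO2 (1.40 ± 0.40), UBE2E1 (1.40 ± 0.19), PLPBP (1.29 ± 0.43) and MTX1 (1.29 ± 0.34). The falls were led by DVL3 (-2.40 ± 0.61), ZNF595 (-1.75 ± 0.12), PNRC1 (-1.72 ± 0.22), WASL (-1.63 ± 0.21) and MEX3C (-1.62 ± 0.15), then HJURP (-1.51 ± 0.53), RDX (-1.44 ± 0.22), ID1 (-1.44 ± 0.25), CSTF1 (-1.43 ± 0.19) and ZMYND8 (-1.41 ± 0.15); ID1 is a target of BMP signalling. Replication dependent histones were the 1 list called, with H2BC5 (1.71 ± 0.24) and H2BC12 (1.21 ± 0.26) rising and H4C3 (-0.89 ± 0.26) falling. Among 13 measured replication dependent histones, 6 rose and 1 fell, or 6 and 1 adjusted over the list alone. Replication dependent histones had a median log2 change of 0.30 and a camera adjusted p = 0.0167, or an adjusted p = 0.432 with an estimated correlation, while the median turned to -0.070 with array medians set equal (camera adjusted p = 0.0142, direction up). In all, 2429 probes were higher and 3756 lower of 30169 tested, 126 and 242 of them by 2-fold or more. Under other scalings at 3 h these counts were 354 and 19300 with array medians set equal, 530 and 8182 with the authors' values and 3226 and 4470 with cyclic loess. Leaving out 1 array ended the calls of LYAR (without control 1 or 3 h array 1, 2 or 3, adjusted p up to 0.0992), RBBP7 (without control 2 or 3 h array 1, adjusted p up to 0.0999), CFL2 (without control 1 or 3 h array 1, 2 or 3, adjusted p up to 0.241), GSTO2 (without control 1 or 3 h array 3, adjusted p up to 0.0622), PLPBP (without control 1, 2 or 3 or 3 h array 2, adjusted p up to 0.218), MTX1 (without control 2, adjusted p up to 0.0655), HJURP (without control 1, 2 or 3 or 3 h array 1, 2 or 3, adjusted p up to 0.141) and H4C3 (without control 1 or 3 h array 1 or 2, adjusted p up to 0.121). Of the 109 named values past the threshold at this time, 35 changed sign when array medians were set equal, a scaling that put the median probe at -0.49 (log2). The treatment notes of all 3 arrays give 2 h.

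At 6 h, on arrays of lower signal, the amino acid response genes were up, with CHAC1 (3.29 ± 0.15), ATF3 (1.83 ± 0.13) and CEBPB (1.47 ± 0.23) rising. Among 18 measured amino acid response genes (ATF4 targets), 7 rose and 0 fell, or 8 and 0 adjusted over the list alone. Amino acid response genes (ATF4 targets) had a median log2 change of 0.32 and a camera adjusted p = 7.91e-05, or an adjusted p = 0.0390 with an estimated correlation, while the median turned to -0.81 with array medians set equal (camera adjusted p = 0.00196, direction up). GDF15 (2.28 ± 0.20), DKK1 (1.67 ± 0.23), LYAR (1.81 ± 0.57), MTX1 (1.62 ± 0.34), ANXA9 (1.52 ± 0.18) and ARFRP1 (1.46 ± 0.37) rose too. PHIP (-1.89 ± 0.12), KCNJ8 (-1.78 ± 0.23), RBPJ (-1.72 ± 0.26), TAOK3 (-1.69 ± 0.18), ZC3HAV1 (-1.63 ± 0.12), AURKA (-1.60 ± 0.24) and WASL (-1.55 ± 0.21) fell. CSTF1, TRIM33 and HOMER1 were not well above background at 6 h and were at least 4.01-, 3.20- and 2.00-fold lower. Replication dependent histones and immediate early genes were up and G2/M genes down. Among 13 measured replication dependent histones, 8 rose and 1 fell, or 8 and 1 adjusted over the list alone. Replication dependent histones had a median log2 change of 0.44 and a camera adjusted p = 7.91e-05, or an adjusted p = 0.0411 with an estimated correlation, while the median turned to -0.12 with array medians set equal (camera adjusted p = 0.00196, direction up). Among 15 measured immediate early genes, 5 rose and 0 fell, or 5 and 0 adjusted over the list alone. Immediate early genes had a median log2 change of 0.17 and a camera adjusted p = 0.00292, or an adjusted p = 0.0390 with an estimated correlation, while the median turned to -0.41 with array medians set equal (camera adjusted p = 0.0193, direction up) and to -0.12 with the authors' values (camera adjusted p = 0.00155, direction up). Among 23 measured G2/M genes, 1 rose and 10 fell, or 2 and 10 adjusted over the list alone. G2/M genes had a median log2 change of -0.30 and a camera adjusted p = 0.0277, or an adjusted p = 0.458 with an estimated correlation. Proteasome subunits and oxidative phosphorylation genes were up, and both lists turned to down when array medians were set equal. Among 16 measured proteasome subunits, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone. Proteasome subunits had a median log2 change of 0.23 and a camera adjusted p = 0.0277, or an adjusted p = 0.0929 with an estimated correlation, while the median turned to -0.93 with array medians set equal (camera adjusted p = 0.639, direction down). Among 18 measured oxidative phosphorylation genes, 5 rose and 0 fell, or 6 and 0 adjusted over the list alone. Oxidative phosphorylation genes had a median log2 change of 0.25 and a camera adjusted p = 0.0332, or an adjusted p = 0.332 with an estimated correlation, while the median turned to -0.96 with array medians set equal (camera adjusted p = 0.919, direction down) and to -0.090 with the authors' values (camera adjusted p = 0.0103, direction up). In all, 2342 probes were higher and 3938 lower of 30165 tested, 124 and 225 of them by 2-fold or more. Under other scalings at 6 h these counts were 242 and 21783 with array medians set equal, 389 and 11735 with the authors' values and 2636 and 3747 with cyclic loess. The call of LYAR (without 6 h array 1, 2 or 3, adjusted p up to 0.0757) was lost with 1 array left out. Of the 106 named values past the threshold at this time, 38 changed sign when array medians were set equal, a scaling that put the median probe at -0.64 (log2). As at 1 h, the share of false calls in the simulated data was above the threshold at 6 h. The main counts at 6 h may therefore also hold more false calls than the threshold allows.

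A trend was fitted over log2 of the treated time, as log2 change per doubling of time, without the control. CHAC1 rose by 1.19 ± 0.04 per doubling, with GDF15 (0.93 ± 0.05), ATF3 (0.77 ± 0.03), ZNF281 (0.64 ± 0.05), GADD45A (0.62 ± 0.05) and NIBAN1 (0.61 ± 0.03) behind it and NUPR1 (0.60 ± 0.04), ZFP36 (0.58 ± 0.03), ZNF24 (0.56 ± 0.05) and CCDC174 (0.56 ± 0.04) next. UTP18 (-0.60 ± 0.05), MSMB (-0.59 ± 0.08), EMP2 (-0.58 ± 0.05), EIF4A3 (-0.56 ± 0.06) and TFG (-0.55 ± 0.07) fell with time, as did TUBB (-0.55 ± 0.05), HSPH1 (-0.53 ± 0.04), ERCC3 (-0.53 ± 0.04), RBBP7 (-0.53 ± 0.10) and PHTF1 (-0.53 ± 0.03). Immediate early genes, amino acid response genes, P-TEFb genes and p53 target genes trended up. Among 15 measured immediate early genes, 9 rose and 0 fell, or 11 and 0 adjusted over the list alone. Immediate early genes had a median log2 change per doubling of 0.10 and a camera adjusted p = 4.02e-07, or an adjusted p = 0.000866 with an estimated correlation. Among 18 measured amino acid response genes (ATF4 targets), 8 rose and 2 fell, or 9 and 2 adjusted over the list alone. Amino acid response genes (ATF4 targets) had a median log2 change per doubling of 0.074 and a camera adjusted p = 3.14e-06, or an adjusted p = 0.0163 with an estimated correlation. Among 13 measured P-TEFb and transcription elongation genes, 4 rose and 0 fell, or 5 and 0 adjusted over the list alone. P-TEFb and transcription elongation genes had a median log2 change per doubling of 0.068 and a camera adjusted p = 0.0108, or an adjusted p = 0.0341 with an estimated correlation. Among 23 measured p53 target genes, 9 rose and 5 fell, or 9 and 5 adjusted over the list alone. p53 target genes had a median log2 change per doubling of 0.077 and a camera adjusted p = 0.0181, or an adjusted p = 0.0794 with an estimated correlation. G1/S genes and heat shock genes trended down. Among 21 measured G1/S and DNA replication genes, 1 rose and 15 fell, or 1 and 16 adjusted over the list alone. G1/S and DNA replication genes had a median log2 change per doubling of -0.15 and a camera adjusted p = 0.000581, or an adjusted p = 0.0186 with an estimated correlation. Among 13 measured heat shock genes, 2 rose and 9 fell, or 2 and 9 adjusted over the list alone. Heat shock genes had a median log2 change per doubling of -0.11 and a camera adjusted p = 0.0193, or an adjusted p = 0.228 with an estimated correlation. In all 5108 probes trended up and 4647 down of 30166. The numbers up and down were 7785 and 2120 with array medians set equal, 5162 and 3349 with the authors' values and 5930 and 4211 with cyclic loess. In the main fit the balance was the other way among the 9821 named genes tested, with 1234 up and 2461 down. Within the 9 arrays at 2, 4 and 12 h the trend was called for 12071 probes and within the 9 at 1, 3 and 6 h for 2107; 321 were called up in both, against 129 for independent lists, 346 down in both, against 302, and 458 in opposite directions, with a correlation across probes, which are not independent replicates, of 0.0943. At least 6 lists were called in 11 of 100 splits of the treated arrays, the real split among them, so chance cannot be excluded for their number. All 6 lists kept their trend within 2, 4 and 12 h. Within 1, 3 and 6 h the calls of p53 target genes (median 0.0070, camera adjusted p = 0.255), heat shock genes (-0.099, 0.163) and P-TEFb genes (-0.040, 0.786) were lost, the median of heat shock genes staying near its size over all treated arrays and that of P-TEFb genes turning below 0, and amino acid response genes were called up by camera (0.0388) with a median of -0.0090.

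Times measured at the same signal level were also compared with each other, in tests chosen after the data were seen. Amino acid response genes were higher at 12 h than at 4 h, with a median log2 difference of 0.74 and an adjusted p = 1.76e-09, or an adjusted p = 0.00427 with an estimated correlation. They were also higher at 6 h than at 3 h, both on arrays of lower signal, with a median log2 difference of 0.30 and an adjusted p = 6.03e-08, or an adjusted p = 0.00479 with an estimated correlation. Immediate early genes were higher at 6 h than at 1 h, with a median log2 difference of 0.82 and an adjusted p = 1.67e-09, or an adjusted p = 0.000186 with an estimated correlation. In single probes, 4 h differed from 2 h for 21 higher and 67 lower, and 12 h from 4 h for 3891 and 2952. In the fit of the 12 arrays of higher signal these steps gave 480 and 11891 probes in all. On the arrays of lower signal, 3 h differed from 1 h for 923 and 1323 probes and 6 h from 3 h for 1315 and 1612.

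Changes at different times overlapped. At 2 and 4 h 232 probes were up in both and 734 down in both, against 14.8 and 66.7 for independent lists, and none went opposite ways. At 4 and 12 h the values were 253 and 761 against 122 and 202, with 162 opposite. The covariance of log2 changes was 0.0604 for 2 and 4 h and 0.0361 for 4 and 12 h, against 0.00328 and 0.00329 when unchanged groups were simulated against shared controls, and the correlations of 0.822 and 0.342 stood beside simulated values of 0.470 and 0.390. In these simulations no probe was called at both times with the same sign. That holds no test of the overlap of calls, because unchanged groups give almost no calls at either time. In a test chosen after the data were seen, with 1 control array used for 1 of the times and the other 2 for the other, in all 6 ways, the covariance was 0.0447 to 0.0563 for 2 and 4 h and 0.0204 to 0.0310 for 4 and 12 h. The probes then up in both were 2 to 79 and 16 to 105, and those down in both 23 to 362 and 85 to 350, each way above the number for independent lists (at most 7.51, 45, 27.4 and 93.7), with up to 17 and 156 opposite. Across all 7 groups 16506 of 30165 probes differed, and on average over the 6 treated times 1230 were higher and 2320 lower, a count that was 1934, 1572 or 1955 without control replicate 1, 2 or 3. Higher and lower on average were 468 and 18798 with array medians set equal, 309 and 7633 with the authors' values and 3046 and 4135 with cyclic loess.

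DNMT1, the maintenance DNA methyltransferase that azacytidine traps, fell at 4 h (-0.43 ± 0.14, adjusted p = 0.0453) and 12 h (-0.58 ± 0.14, adjusted p = 0.00495). Its log2 change was -0.26 ± 0.14 at 2 h, 0.06 ± 0.15 at 3 h and 0.15 ± 0.14 at 6 h, none past the threshold, and it was higher at 1 h (0.52 ± 0.14), where the sign turned when array medians were set equal. The 4 h call did not hold for DNMT1 (without control 1 or 2 or 4 h array 1, 2 or 3, adjusted p up to 0.213). DNMT3A and DNMT3B passed the test at no time, with changes at 12 h of -0.07 ± 0.11 and -0.02 ± 0.13. These are transcript levels, not the amounts of enzyme.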

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

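All tests in this part were chosen after the results they bear on were seen. The arrays at 3 h lay apart from those at 2 h and 4 h, with 4967 probes differing from the mean of those times. A response at 3 h that had gone by 6 h is argued against as the only source, because 79% of these probes had the same sign for 6 h minus 12 h. Both contrasts set arrays of lower signal against arrays of higher signal. Whether such a response added to the difference in some probes therefore cannot be told from these signs. Less messenger RNA in the cells is argued against by the positive control spots, a signal outside the gene probes, whose ratio of the 1, 3 and 6 h arrays to the others was 0.488 (median of 300 spots, quartiles 0.428 to 0.586), provided that these were added in a fixed amount. A weaker signal on the 1, 3 and 6 h arrays stays open as a candidate explanation, since 90.5% of the probes had the same sign for 1 h minus control, which shares no array with the contrast that picked them. A response shared by 1, 3 and 6 h and absent at 2, 4 and 12 h was not tested apart from it, as no untreated array has the lower signal.

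Amino acid response genes were higher at 12 h than at 4 h by a median log2 difference of 0.74, which the test of the difference picked out. No 1, 3 or 6 h array enters this difference (adjusted p = 0.00427 with an estimated correlation), so it holds no test of the weaker signal of those arrays. A rise of the unfolded protein response genes as listed is argued against. The 13 genes had a median log2 change of -0.23 at 12 h, with 0 rising and 3 falling. The 5 and 95% points of a bootstrap over genes, which are not independent replicates, were -0.43 and -0.048. None of the 13 is on the amino acid list, so a branch of the unfolded protein response that acts through ATF4 was not tested. Time in culture cannot be told apart from azacytidine for this rise of 0.74, because the untreated arrays carry no stated time. A response of the cells to azacytidine, the exposure that the design names, stays open as a hypothesis beside it.

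Other differences between times at the higher signal level were picked out by a test of the difference. Between 2 h and 4 h 88 probes differed (480 in the fit of the 12 arrays of higher signal), and immediate early genes were higher at 4 h by a median of 0.19 (log2, camera adjusted p = 1.64e-07, or 0.000658 with an estimated correlation). Between 4 h and 12 h 6843 probes differed (11891 in that fit). The p53 target genes were higher at 12 h than at 4 h by a median of 0.18 (camera adjusted p = 0.00276, or 0.0332 with an estimated correlation), and proteasome subunits were lower, at -0.37 (camera adjusted p = 0.00276, or 0.0332 with an estimated correlation). ELF3 fell at 4 h (-1.48) and rose at 12 h (0.89), a log2 difference of 2.37. TRIB3 fell at 4 h (-1.02) and rose at 12 h (1.77), a log2 difference of 2.79. YTHDF2 fell at 4 h (-1.72) and rose at 12 h (0.53), a log2 difference of 2.24.

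Other splits of the arrays were counted for each test. The 6 arrays of a comparison with the control make 10 splits, too few for a share under 0.05. The real split gave the most probes at each time, 1 of 10, with 5914 at 1 h (highest other 60), 1226 at 2 h (highest other 0), 6185 at 3 h (highest other 1), 3647 at 4 h (highest other 1), 6280 at 6 h (highest other 1) and 5328 at 12 h (highest other 0). The same held for the step from 2 h to 4 h, with 88 probes against 1, and from 4 h to 12 h, with 6843 against 95. For the lists the real split gave 2 at 1 h (as many in 2 of the 10, highest other 3), 4 at 2 h (as many in 6 of the 10, highest other 7), 1 at 3 h (as many in 2 of the 10, highest other 2), 5 at 4 h (as many in 3 of the 10, highest other 6), 6 at 6 h (as many in 2 of the 10, highest other 8) and 10 at 12 h (as many in 1 of the 10, highest other 6). Over 100 drawn splits chance can be excluded for probes differing across the 7 groups (16506, highest other 2), a count reached by 1 of the 100, the real split itself. The same share held for the average over the treated times (3550, highest other 57). It also held for the slope over time (9755, highest other 4916), where only treated arrays were split. These splits moved single arrays between groups and so broke up the groups of 3. They therefore show that arrays differed by group, and cannot decide whether levels followed time or treatment. For the 6 lists with a slope chance cannot be excluded, as 11 of 100 splits gave as many (highest other 9).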

How the results depend on the processing

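Fits of the 12 arrays of higher signal, slopes within each signal level, values relative to the median probe and the background fit with flagged spots kept were chosen after the data were seen. Signal over background limits what the 1, 3 and 6 h arrays show, and the signs of named genes that turned under other scalings were all at these times. The cause was not tested for the changed values below, except where the setting itself shows it.

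With array medians set equal, probes called were 20091 (268 higher, 19823 lower) at 1 h, beside 2340 and 3574 with quantile normalization, 5420 (304 higher, 5116 lower) at 2 h, beside 308 and 918 with quantile normalization, 19654 (354 higher, 19300 lower) at 3 h, beside 2429 and 3756 with quantile normalization, 8655 (930 higher, 7725 lower) at 4 h, beside 1448 and 2199 with quantile normalization, 22025 (242 higher, 21783 lower) at 6 h, beside 2342 and 3938 with quantile normalization and 10458 (1786 higher, 8672 lower) at 12 h, beside 2550 and 2778 with quantile normalization, and 19266 (468 higher, 18798 lower) on average, beside 1230 and 2320. The slope was called for 9905 (7785 up, 2120 down), beside 5108 and 4647. Lists called were 0 at 1 h and 2, 2 and 2 at 2, 3 and 4 h. The median probe then stood at -0.51 at 1 h, -0.10 at 2 h, -0.49 at 3 h, -0.14 at 4 h, -0.64 at 6 h and -0.15 at 12 h (log2), and at -0.43 at 1 h, -0.10 at 2 h, -0.37 at 3 h, -0.083 at 4 h, -0.54 at 6 h and -0.17 at 12 h with the authors' values. Of 683 named values past the threshold 119 changed sign with array medians set equal, 55 when taken relative to the median probe, and none of them at 2, 4 or 12 h. The list medians that turned were -0.13 for replication dependent histones at 1 h (camera adjusted p = 0.0796, direction up), -0.0062 for ribosome biogenesis genes at 2 h (camera adjusted p = 0.301, direction up), -0.044 for proteasome subunits at 2 h (camera adjusted p = 0.199, direction up), -0.070 for replication dependent histones at 3 h (camera adjusted p = 0.0142, direction up), -0.044 for genes with promoter methylation in breast tumours at 4 h (camera adjusted p = 0.0642, direction up), -0.41 for immediate early genes at 6 h (camera adjusted p = 0.0193, direction up), -0.81 for amino acid response genes (ATF4 targets) at 6 h (camera adjusted p = 0.00196, direction up), -0.12 for replication dependent histones at 6 h (camera adjusted p = 0.00196, direction up), -0.93 for proteasome subunits at 6 h (camera adjusted p = 0.639, direction down), -0.96 for oxidative phosphorylation genes at 6 h (camera adjusted p = 0.919, direction down), -0.0016 for immediate early genes at 12 h (camera adjusted p = 0.0118, direction up) and -0.10 for apoptosis regulators at 12 h (camera adjusted p = 0.0142, direction up).

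The genes called higher at 1 h whose log2 change turned below 0 with array medians set equal were DNMT1 -0.15, PHLDA3 -0.23, CCNG1 -0.37, TP53I3 -0.30, XPOT -0.071, GARS1 -0.24, MTHFD2 -0.64, PDIA6 -0.15, HSP90AA1 -0.069, HSPH1 -0.50, RAB31 -0.12, MCM2 -0.35, MCM6 -0.12, BIRC5 -0.11, CDK1 -0.45, CENPF -0.54, H2AC18 -0.25, TDG -0.11, HDAC2 -0.54, FBL -0.38, PUS1 -0.44, TRMT1 -0.52, TK1 -0.27, UCK2 -0.52, DCK -0.33, WDR12 -0.67, NAT10 -0.76, POLR1B -0.82, RPL8 -0.47, RPL18 -0.53, DHCR7 -0.58, DHCR24 -0.53, LDHA -0.24, BAK1 -0.21, CASP7 -0.64, PRDX1 -0.087, GCLM -0.50, MSH2 -0.57, PSMB5 -0.21, PSMA7 -0.31, PSMB3 -0.47, PSMA5 -0.44, ATP5PB -0.22, CYC1 -0.52, ATP5F1B -0.35 and CCNT2 -0.16.

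The genes called higher at 3 h whose log2 change turned below 0 with array medians set equal were IER2 -0.47, PHLDA3 -0.14, XPOT -0.23, GARS1 -0.64, PDIA6 -0.15, HSP90AA1 -0.42, RAB31 -0.41, MCM2 -0.46, GINS2 -0.55, H3C1 -0.049, HDAC2 -0.51, TDG -0.47, NSUN2 -0.086, PUS1 -0.37, SSX2 -0.41, CST6 -0.16, SOD2 -0.52, TK1 -0.60, RRM2 -0.078, WDR12 -0.59, RPL8 -0.26, RPL18 -0.31, RPL19 -0.25, DHCR24 -0.34, PGK1 -0.21, CASP7 -0.51, BAK1 -0.27, PSMB5 -0.18, PSMA3 -0.60, PSMB6 -0.48, PSMA5 -0.56, CYC1 -0.57, ATP5PB -0.44, COX4I1 -0.50 and CDH1 -0.37.

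The genes called higher at 6 h whose log2 change turned below 0 with array medians set equal were IER2 -0.36, ZFP36 -0.87, SESN2 -0.18, CDKN1A -0.53, PHLDA3 -0.32, PDIA6 -0.72, AREG -0.81, H3C1 -0.13, H2BC8 -0.12, H2BC12 -0.40, TRMT61A -0.46, DKC1 -1.01, CST6 -0.29, ID4 -0.76, RASSF1 -0.66, SOD2 -0.92, UCK1 -0.94, TK1 -0.80, RPL8 -0.63, RPLP1 -0.42, RPL19 -0.60, DHCR24 -0.64, LDLR -0.85, ADM -0.14, PGK1 -0.59, PMAIP1 -0.41, BAX -0.86, PRDX1 -0.35, PSMB5 -0.74, PSMA7 -0.64, PSMB6 -0.69, PSMA5 -0.75, ATP5F1B -0.39, CYC1 -0.76, NDUFS1 -0.85, NDUFB8 -0.85, MEPCE -0.57 and CDK9 -0.10. At 6 h camera's direction itself turned for proteasome subunits (median -0.93) and oxidative phosphorylation genes (median -0.96).

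With the authors' values, probes called were 9500 (436 higher, 9064 lower) at 1 h, 1439 (80 higher, 1359 lower) at 2 h, 8712 (530 higher, 8182 lower) at 3 h, 3428 (530 higher, 2898 lower) at 4 h, 12124 (389 higher, 11735 lower) at 6 h and 5271 (1007 higher, 4264 lower) at 12 h and 7942 (309 higher, 7633 lower) on average, and lists called 2 at 2 h and 2 at 3 h. Signs turned for TRMT1 at 1 h (-0.011), POLR1B at 1 h (-0.059), DKC1 at 6 h (-0.014), RASSF1 at 6 h (-0.075), SOD2 at 6 h (-0.11) and UCK1 at 6 h (-0.032). Cyclic loess gave 4165 (1285 higher, 2880 lower) probes at 2 h, 7427 (2766 higher, 4661 lower) probes at 4 h and 8570 (4845 higher, 3725 lower) probes at 12 h and 7181 on average, with 6 lists at 1 h and 3 at 3 h, and turned KRT18 at 3 h to 0.11.

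Background subtraction without offset left 494 probes at 2 h. Without a filter 7, 0 and 3 lists were called at 2, 3 and 4 h. Over the fewer probes good on all 21 arrays, 3797, 2405 and 3500 passed at 3, 4 and 6 h, 2363 on average, 5980 for the slope and 9423 across groups. Array weights gave 8673, 10482 and 13218 at 2, 4 and 12 h and 9735 on average. Fits of only the 6 arrays compared gave 3156, 5486 and 7973 at 1, 2 and 4 h. With a log2 change of at least 1 also required, 365, 64, 368, 240, 349 and 482 passed at 1, 2, 3, 4, 6 and 12 h. With the estimated correlation 1, 0, 0, 0, 3 and 3 lists were called at these times, and with fry, which does not compare a list with other genes, 14, 9, 12, 11, 18 and 19, and 21 for the slope. The 12 arrays of higher signal alone gave 4576, 8701 and 9237 probes at 2, 4 and 12 h, 7219 on average and 3 lists at 4 h.

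The slope within 2, 4 and 12 h gave 10 lists, and that within 1, 3 and 6 h gave 2107 probes and 6 lists. The list trends lost within 1, 3 and 6 h were those of p53 target genes (median 0.0070, camera adjusted p = 0.255), heat shock genes (-0.099, 0.163) and P-TEFb genes (-0.040, 0.786). Slopes turned within 2, 4 and 12 h for CENPF 0.022, H2BC5 0.0038, TDG 0.034, MBD4 0.072, NOP2 0.15, IL6 -0.066, RPL19 0.076 and ATP5F1A 0.017, and within 1, 3 and 6 h for HSP90B1 0.013, SDF2L1 0.062, SLC30A1 -0.17, ICAM1 0.10, DHCR24 0.012, ID1 -0.19, ID3 -0.094, PMEPA1 -0.076, HMOX1 -0.051, TXNRD1 -0.11, PARP1 0.044, PSMA3 0.025, CCNT1 -0.040 and BRD4 -0.025. A further 24 named slopes lost their call within 2, 4 and 12 h, and 56 within 1, 3 and 6 h.

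With 1 array left out, probes called ran from 3546 to 6191 at 1 h, 318 to 854 at 2 h, 4205 to 5626 at 3 h, 1626 to 2973 at 4 h, 4302 to 5691 at 6 h and 3301 to 5450 at 12 h, 1572 to 4429 on average, 7773 to 9999 for the slope and 14595 to 17407 across groups. Lists called ran from 1 to 3 at 1 h, 3 to 7 at 2 h, 2 to 5 at 4 h, 4 to 8 at 6 h, 10 to 12 at 12 h and 5 to 6 for the slope, and stayed at 1 at 3 h. Values of named genes that lost their call numbered 177 with the authors' values, 143 with array medians, 135 without offset, 96 with only 6 arrays, 57 without filter, 46 with weights, 44 with loess and 18 with trend and robust options. Of the signs that turned, 6, 54 and 1 are among these losses with the authors' values, array medians and loess, and 65 were called with the other sign with array medians. Without the 5 arrays whose note gives another time 48 were lost and none turned. With 1 array left out 723 refitted values of named genes lost their call, 9 gained it and none turned.

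With the replicate number as a block (replicate block) the counts were 5662, 1082, 5904, 3319, 6046 and 5135 at 1, 2, 3, 4, 6 and 12 h, none moved by over 1.5 times, and 17 named values lost their call. The numbers do not pair the arrays: over 63 pairs of arrays with the same number the correlation of deviations from the group means had a median of -0.0127 (range -0.396 to 0.391), 5 above 0.1, and in 19 pairs an array correlated best with its own number. Between arrays of different numbers the correlation reached 0.502, for replicate 2 at 4 h with a 12 h array. Some deviations were thus shared between groups, from a source that was not tested. A slide or scan batch as a block was not run, because the files give none.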

Other observations

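The zinc finger family below was picked by its symbol after gene names had been seen, its tests were written before their results, and no other test was added here. None of the lists in the next paragraphs passed the test at any time, the lowest camera adjusted p being 0.0534. At 12 h MSH2 (-1.03 ± 0.17), PARP1 (-0.80 ± 0.10) and APEX1 (-0.69 ± 0.15), which act in DNA repair, fell. Of 18 measured DNA repair genes, 0 rose and 4 fell at 12 h (0 and 4 adjusted over the list alone, median log2 change -0.17, camera adjusted p = 0.0534). HMOX1, not well above background in the control, was at least 1.90-fold higher, and TXNRD1 (0.85 ± 0.11) rose, both genes of the oxidative stress response. Of 12 measured NRF2 target genes, 2 rose and 0 fell at 12 h (2 and 0 adjusted over the list alone, median log2 change 0.0075, camera adjusted p = 0.0828). The chaperone genes HSP90B1 (-1.23 ± 0.15) and MANF (-0.75 ± 0.13) fell. Of 13 measured unfolded protein response genes, 0 rose and 3 fell at 12 h (0 and 3 adjusted over the list alone, median log2 change -0.23, camera adjusted p = 0.122). Glycolysis genes ALDOC (-1.03 ± 0.17) and LDHA (-0.89 ± 0.15) fell. Of 13 measured hypoxia and glycolysis genes, 1 rose and 5 fell at 12 h (1 and 5 adjusted over the list alone, median log2 change -0.21, camera adjusted p = 0.122). Besides PGR, GREB1 (-0.85 ± 0.17) fell at 12 h, and the growth factor gene AREG fell at 2 h (-0.96 ± 0.14) and 4 h (-0.81 ± 0.14). Of 16 measured estrogen induced genes, 0 rose and 5 fell at 12 h (1 and 6 adjusted over the list alone, median log2 change -0.30, camera adjusted p = 0.0825).

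The BMP target ID1 fell at 2 h (-1.14 ± 0.25) and 4 h (-1.34 ± 0.25), and ID3, not well above background at 4 h, was at least 1.61-fold lower there and rose at 12 h (0.90 ± 0.16). Of 14 measured TGF-beta and BMP response genes, 2 rose and 1 fell at 12 h (2 and 3 adjusted over the list alone, median log2 change 0.063, camera adjusted p = 0.444). The histone methyltransferase gene SETDB1 fell at 2 h (-0.91 ± 0.15) and 4 h (-1.17 ± 0.15), and at 12 h HDAC2 (-0.73 ± 0.16) fell. Of 14 measured genes of the DNA methylation machinery, 1 rose and 4 fell at 12 h (1 and 4 adjusted over the list alone, median log2 change -0.099, camera adjusted p = 0.583). Of RNA modification enzymes, TRMT61A (0.91 ± 0.12) rose and NSUN2 (-0.83 ± 0.19) fell at 12 h. Of 14 measured RNA cytosine methyltransferases and RNA modification enzymes, 5 rose and 3 fell at 12 h (6 and 4 adjusted over the list alone, median log2 change 0.13, camera adjusted p = 0.211). IFITM1 fell at 2 h (-0.68 ± 0.11), 4 h (-0.64 ± 0.11) and 12 h (-0.89 ± 0.11). Of 13 measured interferon induced genes, 0 rose and 3 fell at 12 h (0 and 4 adjusted over the list alone, median log2 change -0.068, camera adjusted p = 0.543). Of 11 measured NF-kappaB target genes, 0 rose and 0 fell at 12 h (0 and 0 adjusted over the list alone, median log2 change 0.033, camera adjusted p = 0.548). Of 15 measured genes of pyrimidine and nucleoside metabolism, 1 rose and 3 fell at 12 h (1 and 3 adjusted over the list alone, median log2 change -0.13, camera adjusted p = 0.670). Of 10 measured genes of cytosolic ribosomal proteins, 3 rose and 1 fell at 12 h (3 and 1 adjusted over the list alone, median log2 change 0.22, camera adjusted p = 0.0788). Of 6 measured cancer testis and germline genes, 0 rose and 0 fell at 12 h (0 and 0 adjusted over the list alone, median log2 change 0.10, camera adjusted p = 0.397). In lists of other cell types, of 5 measured basal and myoepithelial genes, 0 rose and 0 fell at 12 h (0 and 0 adjusted over the list alone, median log2 change -0.060, camera adjusted p = 0.932), and of 8 measured fibroblast and mesenchymal genes, 0 rose and 1 fell at 12 h (0 and 1 adjusted over the list alone, median log2 change -0.11, camera adjusted p = 0.614). Of 5 measured leukocyte genes, not tested as a list, 0 rose and 0 fell at 12 h (1 and 0 adjusted over the list alone), while CD68 was called lower at 1 h (adjusted p = 0.0203) and 3 h (adjusted p = 0.0308) and CSF1R at 3 h (adjusted p = 0.0396), both not well above background there. MT1F fell at 2 h (-0.82 ± 0.14), 4 h (-0.65 ± 0.14) and 12 h (-0.95 ± 0.14), and of 3 measured members of that list, also not tested, 1 rose and 1 fell at 12 h (1 and 1 adjusted over the list alone).

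Genes of zinc finger transcription factors with a ZNF symbol, 230 measured, had a median log2 change of -0.23 at 2 h, where 42 fell (18.3%, against 3.41% of other genes), and of -0.20 at 4 h, where 67 fell (29.1% against 11.8%). At 12 h the median was 0.00042, at percentile 99.1 of matched random lists, with 28 rising and 8 falling (3.48%, against 14.4%), and on the arrays of lower signal it was -0.21, -0.29 and -0.17 at 1, 3 and 6 h. Dim probes are argued against as the source, since among 10000 random lists matched on mean expression the family's median lay at percentile 0 at 2 h and at 4 h. Scaling of the arrays is argued against too, because relative to the median probe the family stayed at -0.25 or lower at these times under array medians, cyclic loess and the authors' values. Short-lived transcripts lost early under azacytidine, which enters RNA, may underlie the pattern, a hypothesis left untested because half-lives were not used here.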
